A study of Ambystoma mexicanum with 18 samples.

How the data were processed

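RNA was sequenced from axolotl (Ambystoma mexicanum) forelimb tissue taken at the plane of a mid-forearm amputation, either at once (0 h) or 24 h later. The axolotl is a salamander that regrows amputated limbs. Each sample pooled tissue pieces of about 2 mm from 5 wildtype subadult animals. Part of each cleared lysate was kept as the input. The rest was separated on a 17.5 to 50% sucrose gradient and collected as 3 pools. The free/RNP pool ran from ribonucleoprotein particles to the small ribosomal subunit, the light polysome pool held monosomes and disomes, and the heavy polysome pool held mRNAs with 3 or more ribosomes. The amount of an mRNA in heavy polysomes is commonly read as a measure of its translation.

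Groups were taken from the sample titles and the labels for time and sample type. They gave 8 groups (4 kinds of sample at 2 times) of 2 libraries each, 16 libraries in all, and 2 bulk tissue samples whose values were not analysed here. Each replicate number carried 1 date code in the labels, the same for all kinds of sample and both times, so the numbers paired the samples by day. The 4 libraries of one time and one replicate number came from 1 lysate, so the 16 libraries stem from 4 tissue pools. This pairing was checked in the counts. The deviations of same-numbered libraries from their group means correlated across features with r between 0.0927 and 0.297 over all pairs of groups, and between 0.187 and 0.229 for the 0 h and 24 h groups of the same kind of sample. Features are not independent replicates in these correlations. The p-values below rest on a spread pooled over all 8 groups and moderated across features. The model behind them treats the 16 libraries as independent, though only 2 pools per time stand behind each comparison. With 2 pools against 2, an exact permutation test of a single value could not go below p = 0.33, so no such test was run.

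The deposited expected counts are estimates of reads per assembled gene, which the submitters' processing notes tie to RSEM with Bowtie2, after FastQC and Trimmomatic 0.36. The transcriptome the reads were aligned to is not given in the sources used here. The deposited table held 473284 gene rows and 89 rows for ERCC spike-ins, which are synthetic RNAs added in known amounts. All expected counts in the deposited table were already whole numbers, so rounding changed none of them. Of the gene rows, 4519 had no count in any library and 15264 had a count in all 16. The deposited spike-in-normalized values were a straight-line transform of the counts of each library, found by fitting each deposited column on its counts. For the gradient pools the multiplier was the inverse slope of a line through the ERCC counts of the library and the heavy polysome library at 0 h of the same replicate, with 3 further spike-in species at 0. The input libraries at 0 h had a multiplier of 1. The multipliers of the 24 h input libraries were 1.22 and 0.705 (replicates 1 and 2) and differed from the inverse slopes against input at 0 h, 1.86 and 0.598. The deposited filtered table kept 8136 gene rows and 3 ERCC rows of these normalized values, and 4 further columns of that table, named as totals, were not used here. The kept gene rows held 83.1 to 97.6% of the gene counts of each library.

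Rows are named by assembly identifiers and the tables pair them with no gene symbols. None of the 473284 identifiers (0) matched the 135668 genes of the RefSeq table for assembly UKY_AmexF1_1, so rows are called features here, no gene is named and no coordinates are given. An assembled feature need not be a whole gene, and reads of near-identical copies may be split between features. The 26 gene lists fixed before the data were examined, among them ribosomal proteins, mTOR pathway components and antioxidant enzymes, could therefore not be tested. The alternative that sums counts over rows sharing a symbol could not be run for the same reason. The naming rule, also set before the data were examined, allowed at most 2 features up and 2 down per comparison when no symbols were given. These were the features with the largest log2 fold change among those with adjusted p under 0.05, a mean of at least 10 CPM (counts-per-million) in a group compared and the same sign of change in both replicates.

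Gene counts per library ran from 1728549 in heavy polysomes at 0 h, replicate 1, to 20758657 in free/RNP at 0 h, replicate 2. The replicate libraries of a group correlated with r between 0.89 and 0.97 across 20985 features on the log2 CPM scale, and no pair held identical values. A count of 0 in a group was bounded by 3 counts over the group's pooled counts. Such bounds and all intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

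Changes were tested with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr with its default limits, which left 43215, and libraries were scaled by TMM. TMM-scaled CPM are relative to the scaled library size, so that the values of a library need not add up to its CPM total. One quasi-likelihood model (glmQLFit, robust, and glmQLFTest) with 1 mean per group was fitted to all 16 libraries, with 8 residual degrees of freedom and a common dispersion of 0.216. It gave 7 comparisons. These were 24 h against 0 h in each of the 4 kinds of sample, the difference of that change between heavy polysomes and input and between heavy polysomes and free/RNP (interaction contrasts), and heavy polysomes against free/RNP at 0 h. Adjusted p-values are Benjamini-Hochberg values over the 43215 features of a comparison, with a threshold of 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Gene counts per ERCC count were compared between times within each replicate, with exact 95% intervals from the ERCC counts.

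The test was tried on simulated counts in which 200 features, drawn only from those above a minimum mean CPM, were changed and all others were level. For an 8-fold change it recovered 94% of the changed features in input, 92.5% in heavy polysomes, 38.5% for heavy polysomes relative to input, 47% for heavy polysomes relative to free/RNP and 91.5% for heavy polysomes against free/RNP at 0 h. For a 2-fold change it recovered at most 1% in any of these 5 comparisons. These rates do not describe features of low level, for which recovery was not measured. Among the tested features, 21114 had an average log2 CPM under 0. False calls in these simulations numbered between 9 and 43 per comparison and fold size, above the nominal rate. They made up 85 to 100% of the calls at 2-fold, 25 to 94.4% at 4-fold and 16.4 to 22.2% at 8-fold.

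Alternatives were DESeq2 1.42.0, RLE size factors, ERCC totals as library sizes, no filter, a filter of 50 counts in 2 libraries, only the features of the deposited filtered table, only the libraries compared, a replicate block (7 residual degrees of freedom), a block per lysate, leaving out each library in turn, and limma 3.58.1 on log2 of the deposited normalized values with a pseudocount of 1. Leaving out a library let the filter, rerun on the remaining 15, pass 56943 to 64927 features. Values without 1 library are therefore given on the 43215 features of the main fit unless the filter is said to be rerun. Further alternatives chosen after seeing the data kept these features when a library was left out, set the TMM factors on the features of the deposited filtered table and added the replicate block to the ERCC, filtered-table and limma settings.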

Results

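The study asked how the mRNAs bound by ribosomes at an axolotl limb wound change in the first day after amputation. RNA was measured in 16 libraries, 2 for each of 8 groups. The groups were the input lysate, the free/RNP pool, the light polysome pool and the heavy polysome pool at 0 h and at 24 h. Total gene counts were 8519424 to 11966179 in the input libraries, 5286933 to 20758657 in free/RNP, 2803793 to 14713638 in light polysomes and 1728549 to 11498303 in heavy polysomes. The 2 shallowest libraries were the heavy polysome library (1728549 counts) and the light polysome library (2803793 counts) at 0 h in replicate 1. When all libraries were thinned to 1728549 gene counts, input libraries still held 90283 to 111845 features with a count and free/RNP libraries 25854 to 34668. Light polysome libraries held 32178 to 41457, and heavy polysome libraries held 52222 and 60695 at 0 h and 47294 and 42835 at 24 h.

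A few features took a large part of the counts in some pools. Feature c1077400_g3 held 54.8% and 28.3% of the free/RNP counts at 0 h (replicates 1 and 2) and 49.1% and 47.5% at 24 h. It held 23.2% and 5.26% of the input counts at 0 h and 14.4% and 12.2% at 24 h. In heavy polysomes its share was 20.4% and 10.1% at 0 h and 5.66% and 3.59% at 24 h, lower at 24 h in both replicates. Feature c1088639_g5 held 20% and 10.6% of the light polysome counts at 0 h and 12% and 5.31% at 24 h, and under 1% of the counts of each input library. Both features were singled out after their values were seen.

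The comparison of input at 24 h with input at 0 h asked which RNAs changed in abundance in the tissue. In input, 1028 features rose and 159 fell out of 43215 tested, with a median log2 fold change of 2.85 among those that rose and −2.47 among those that fell. Feature c1071771_g2 had no count in either 0 h library and 33.5 ± 12.6 CPM (SD, n = 2) at 24 h, at least 340-fold higher (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.14e-18). Feature c1062836_g4 also rose from no count to 10.5 ± 2.2 CPM (SD, n = 2), at least 105-fold. Feature c1074641_g1 fell from 17.2 ± 8.68 to 0.771 ± 0.178 CPM (SD, n = 2), with a log2 fold change of −4.47 and an SE of 0.57. Feature c1072583_g6 fell from 10.5 ± 1.3 to 0.61 ± 0.406 CPM (SD, n = 2), with a log2 fold change of −4.08 and an SE of 0.82. With a replicate block 1844 features rose and 535 fell, and 67.6% of the called features were higher with TMM factors set on the filtered-table features, against 86.6% here. On the filtered-table features alone 759 rose and 530 fell (58.9% higher), and 1026 and 931 with the replicate block added. Without 1 library, on the same 43215 features, the counts were 486 (0 h, replicate 1, 71.4% higher), 718 (0 h, replicate 2), 650 (24 h, replicate 1) and 718 (24 h, replicate 2). The log2 fold change of c1074641_g1 was −5.14 without the 0 h library of replicate 2, and that of c1072583_g6 was −5.24 without the 24 h library of replicate 2. When the filter was rerun c1072583_g6 was lost without the 24 h library of replicate 1.

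The next comparison asked the same of mRNAs in heavy polysomes, the pool with 3 or more ribosomes per mRNA. There 2181 features rose and 186 fell between 0 h and 24 h, with a median log2 fold change of 2.08 among those that rose and −2.22 among those that fell. The most strongly raised were c1089890_g5, from no count to 143 ± 109 CPM (SD, n = 2), and c1014346_g1, from no count to 120 ± 94 CPM (SD, n = 2). These were at least 779-fold and at least 652-fold higher, with adjusted p = 0.0327 and 0.0217 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The SDs reflect values over 3 times as high in replicate 1 as in replicate 2. Feature c1080778_g1 fell from 28.3 ± 10.5 to 1.8 ± 0.364 CPM (SD, n = 2), a log2 fold change of −3.96 with an SE of 0.58, and c1090859_g5 fell from 32.6 ± 1.12 to 2.7 ± 1.67 CPM, a log2 fold change of −3.58 with an SE of 0.51. The excess of raised features depended on the scaling. With TMM factors set on the features of the deposited filtered table, 1124 features rose and 1258 fell (47.2% higher against 92.1%) and the median over all tested features moved from −0.15 to −0.84, with RLE size factors 1761 rose and 579 fell, and with a replicate block 3833 rose and 806 fell. On the filtered-table features alone 1185 rose and 1126 fell. The count on the same 43215 features was 987 without the 0 h library of replicate 1 and 1268 without the 24 h library of replicate 2. On these features c1089890_g5 did not pass the threshold without any 1 of the 4 heavy polysome libraries, and c1014346_g1 did not without either 0 h library. With the filter rerun c1089890_g5 was lost only without a 0 h library, and c1014346_g1 in no such fit. Feature c1089890_g5 was also lost with RLE factors and with TMM factors set on the filtered-table features. Both features passed without a filter on low counts. With a replicate block their adjusted p-values were 2.22e-63 and 9.64e-56 by edgeR's quasi-likelihood test. At 24 h both were higher in replicate 1 than in replicate 2 in the other kinds of sample too. In input the values were 125 and 20.1 CPM for c1089890_g5 and 42.6 and 9.32 CPM for c1014346_g1. The block takes up this difference between tissue pools, so these p-values do not measure the spread between pools. The log2 fold change of c1090859_g5 was −4.41 without the 24 h library of replicate 2, and that of c1080778_g1 was −4.63 without the 0 h library of replicate 2.

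**Figure D1:**
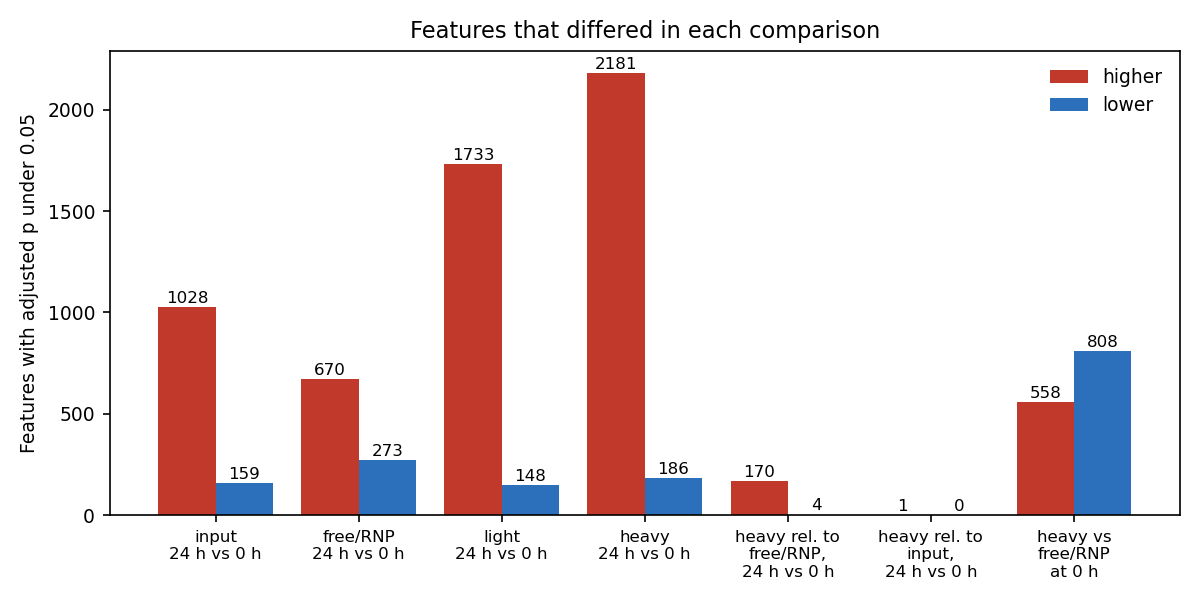
Number of features (vertical axis) with an adjusted p under 0.05 in each of the 7 comparisons (horizontal axis), by edgeR's quasi-likelihood test with TMM scaling and no replicate block. Red bars count features that were higher and blue bars features that were lower at 24 h, or in heavy polysomes at 0 h for the last pair, from 2181 higher in heavy polysomes to 1 for heavy polysomes relative to input.

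In light polysomes, which hold monosomes and disomes, 1733 features rose and 148 fell. Feature c1071771_g2, the most raised in input, was also the most raised there, from no count to 61.5 ± 8.2 CPM (SD, n = 2), at least 411-fold higher. Feature c1087521_g1 rose from no count to 30.3 ± 5.49 CPM (SD, n = 2), at least 202-fold higher (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.62e-14). Feature c1074641_g1 fell with a log2 fold change of −4.84 (SE 0.60) and c1090494_g5 with −3.69 (SE 0.55), from 127 and 35.7 CPM in the 2 libraries at 0 h to 6.28 ± 0.613 CPM at 24 h (SD, n = 2). The log2 fold change of c1090494_g5 was −2.72 and −4.68 without the 0 h library of replicate 1 or 2, and that of c1074641_g1 was −5.63 without the 0 h library of replicate 2. With a replicate block 3314 features rose and 402 fell (721 and 106 with ERCC totals as library sizes as well), while 71.0% of the called features were higher with RLE size factors and 62.1% with TMM factors set on the filtered-table features, against 92.1% here. On the filtered-table features alone 1027 rose and 734 fell. Counts on the same 43215 features were 666 and 990 without the 0 h library of replicate 1 or 2, and 1017 and 1071 without the 24 h library of replicate 1 or 2.

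In the free/RNP pool, which holds mRNAs not bound by a full ribosome, 670 features rose and 273 fell. Feature c1087521_g1 rose from no count to 18.2 ± 1.18 CPM (SD, n = 2), at least 72.5-fold, and c1034021_g1 from no count to 11.9 ± 3.44 CPM, at least 42.2-fold. Feature c1072572_g4 fell from 30.1 ± 6.61 to 1.76 ± 0.411 CPM (log2 fold change −4.13, SE 0.67), and c1087236_g1 fell from 26.2 ± 8.24 to 2.07 ± 1.42 CPM (log2 fold change −3.80, SE 0.62). Their adjusted p-values were 7.46e-06 and 8.47e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With a replicate block 1285 features rose and 923 fell, and among the features of the deposited filtered table alone 698 rose and 641 fell. With ERCC totals as library sizes and a replicate block 846 rose and 52 fell. The count on the same features was 542 (450 higher, 92 lower) without the 24 h library of replicate 2, and 855 (423 higher, 432 lower) without the 0 h library of replicate 1, which turns the balance. Over all edgeR and DESeq2 alternatives with calls, 49.0 to 94.2% of them were higher. The log2 fold change of c1087236_g1 was −4.52 and −3.06 without the 24 h library of replicate 1 or 2.

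Across the 4 kinds of sample, 3251 features changed in at least 1, and 503 rose and 46 fell in all 4. Only 2 features rose in one kind and fell in another. Of the 1028 features that rose in input, 827 also rose in heavy polysomes, 837 in light polysomes and 562 in free/RNP, where independent lists would share 51.9, 41.2 and 15.9. Of the 159 that fell in input, 74 fell in heavy polysomes, 73 in light polysomes and 86 in free/RNP, where independent lists would share 0.684, 0.544 and 1. The pools of 1 lysate share its tissue, so part of this overlap may come from the shared tissue pools. The independent lists were also taken over all 43215 features, of which 21114 had an average log2 CPM under 0. If such features are seldom called in any comparison, these expected numbers are too low. The features raised in input had median log2 fold changes of 2.85 in input, 2.36 in free/RNP, 2.86 in light polysomes and 2.97 in heavy polysomes. The features lowered in input had medians of −2.47 in input, −2.19 in free/RNP, −1.73 in light polysomes and −1.71 in heavy polysomes. Both sets were chosen by their change in input, which favours larger changes there, so smaller medians in the pools need not mean a weaker response. Across all 43215 features the log2 fold changes in input and heavy polysomes correlated with r = 0.453 and a slope of 0.607, and across the 8136 features of the deposited filtered table with r = 0.823 and a slope of 0.999. Features are not independent replicates in these correlations.

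**Figure D2:**
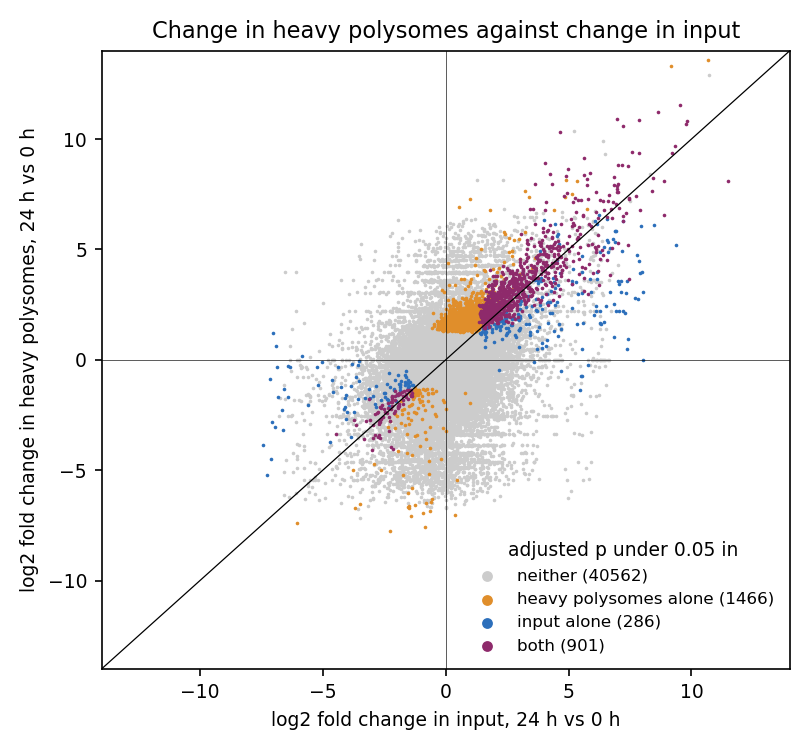
Log2 fold change at 24 h against 0 h in heavy polysomes (vertical axis) and in input (horizontal axis), 1 point for each of the 43215 tested features, with the line of equal change. Colours give the kind of sample in which the adjusted p was under 0.05. Called in both were 827 features that rose and 74 that fell, and their distance from the line was not measured.

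Whether an mRNA changed more in heavy polysomes than in the tissue was asked by the difference between the changes in heavy polysomes and input. Feature c1061563_g2 rose in heavy polysomes relative to input, with a log2 difference of 3.16 (SE 0.60, adjusted p = 0.0322 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its level in input was 80.9 ± 2.14 CPM at 0 h and 76 ± 9.72 CPM at 24 h (SD, n = 2). In heavy polysomes it went from 43.9 ± 7.44 to 366 ± 6.64 CPM, in light polysomes from 65.7 ± 36.2 to 413 ± 15.2 CPM and in free/RNP from 264 ± 108 to 173 ± 3.35 CPM (SD, n = 2). An unadjusted p under 0.05 was found for 1446 of the 43215 features, fewer than would pass if none differed. No other feature passed the adjusted threshold. The count was 139 (125 higher, 14 lower) with a replicate block, 322 (304 higher, 18 lower) with a block per lysate and 46 (45 higher, 1 lower) by DESeq2. The adjusted p of c1061563_g2 was 7.69e-09 with the replicate block and 1.79e-08 by DESeq2, and over all alternatives ran from 1.29e-11 to 1. It was 0.174 by edgeR both with the stricter filter and on the filtered-table features. The feature was also lost without a filter, with ERCC totals and no block, and by limma with or without the block. Leaving out 1 of the 8 input and heavy polysome libraries, on the same 43215 features, kept its log2 difference between 2.94 and 3.30. Its adjusted p was then 0.00725, 0.0227 and 0.0333 without input at 0 h (replicates 1 and 2) or at 24 h (replicate 2), and 0.136 to 0.529 without any other. With the filter rerun, over 56943 to 64697 features, the log2 difference was 2.85 to 3.26 and the adjusted p 0.0502 to 1.

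**Figure D3:**
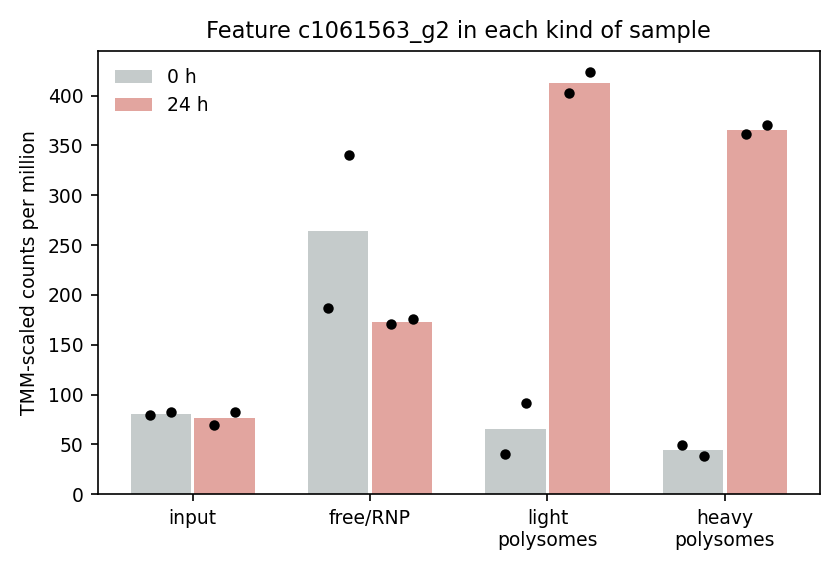
TMM-scaled CPM (vertical axis) of feature c1061563_g2 in each kind of sample (horizontal axis) at 0 h (grey) and 24 h (red). Bars are means of 2 libraries and points are the libraries. The heavy polysome mean was 43.9 at 0 h and 366 at 24 h, and the input mean was 80.9 and 76.

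The difference between the changes in heavy polysomes and free/RNP asked which mRNAs changed differently in the 2 pools. It was higher for 170 features and lower for 4. The 170 had median log2 fold changes of 2 in heavy polysomes, 1.19 in light polysomes, 0.50 in input and −0.74 in free/RNP. Of these 170, 145 were not called in input, 149 rose in heavy polysomes and 15 fell in free/RNP, the last 2 counts coming from the same libraries as the difference itself. Feature c1055716_g1 had a log2 difference of 4.73 (SE 1.11), with 22.8 ± 7.57 and 21.2 ± 1.77 CPM in heavy polysomes at 0 h and 24 h and 3.07 ± 0.469 and 0.171 ± 0.241 CPM in free/RNP (SD, n = 2). In free/RNP it had 7 and 31 counts at 0 h and 1 and 0 at 24 h, so the size of its difference is uncertain. Feature c1068963_g2 had a log2 difference of 4.54 (SE 1.01) and went from 3.2 ± 3.18 to 17.2 ± 6.01 CPM in heavy polysomes and from 3.03 ± 2.07 to 0.571 ± 0.325 CPM in free/RNP, where it had 1 and 6 counts in the libraries at 24 h. Feature c1056993_g1 was lower, with a log2 difference of −2.66 (SE 0.67). It rose in input from 31.3 ± 7.12 to 139 ± 32.5 CPM and in free/RNP from 6.98 ± 6.56 to 34.5 ± 2.48 CPM, and had 11 ± 5.35 and 7.6 ± 1.03 CPM in heavy polysomes. Their adjusted p-values were 0.023, 0.0163 and 0.042 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With a replicate block 1290 features were higher and 82 lower, and with TMM factors set on the filtered-table features 63 and 7 (c1055716_g1 and c1068963_g2 not among them). Without a filter on low counts edgeR called none. Of the 468765 features then tested 4726 had an unadjusted p under 0.05, fewer than would pass if none differed. Leaving out 1 library on the 43215 features gave counts of 1084 and 22 (free/RNP at 0 h, replicates 1 and 2), 3 and 45 (free/RNP at 24 h), 19 and 70 (heavy polysomes at 0 h) and 28 (heavy polysomes at 24 h, replicate 2), and each of the 3 named features was lost in at least 5 of the 8 such fits. In them the log2 difference ran from 3.06 to 8.09 for c1055716_g1 (without free/RNP at 24 h, replicates 2 and 1) and from 3.38 to 6.20 for c1068963_g2 (without free/RNP or heavy polysomes at 0 h, replicate 2). For c1056993_g1 it ran from −4.38 to −2.07 (without free/RNP at 0 h, replicates 2 and 1).

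The same difference grew with the level of a feature. Its median was −0.42 on the log2 scale over the 21114 features with an average log2 CPM under 0, 0.54 over the 2779 features between 3 and 4 and 1.18 over the 332 features above 8. From log2 CPM with a prior count, the medians in these classes were 0, 0.55 and 0.84 in replicate 1, and in replicate 2 they were −0.12, 0.58 and 1.30. With TMM factors set on the filtered-table features the median over all tested features moved from 0.14 to −0.57, a scaling that applies to all features of a library alike. The trend was not particular to the comparison with free/RNP. In the same classes the change in heavy polysomes alone had medians of −0.48, 0.51 and 0.66. Relative to input the medians were −0.52, 0.35 and 0.67, and in free/RNP alone they were 0, −0.13 and −0.53.

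**Figure D4:**
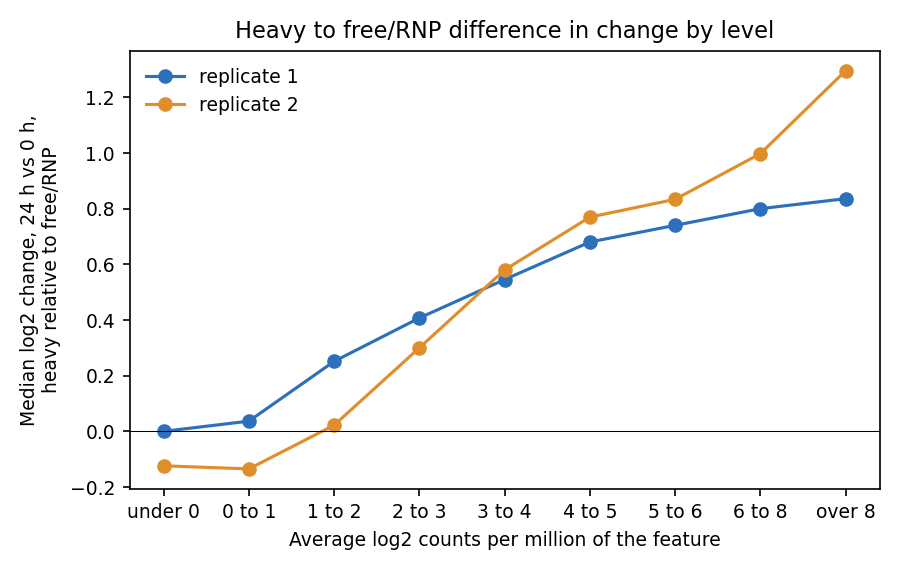
Median log2 change at 24 h against 0 h in heavy polysomes relative to free/RNP (vertical axis) by average log2 CPM of the feature (horizontal axis, classes of 332 to 21114 features), with TMM scaling. Blue points are replicate 1 and orange points replicate 2. Both rose with level, from 0 to 0.84 in replicate 1 and from −0.12 to 1.30 in replicate 2.

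Heavy polysomes were compared with free/RNP at 0 h to place mRNAs in the gradient before the response to amputation. There 558 features were more abundant in heavy polysomes and 808 in free/RNP. The 808 held 76.3% of the free/RNP counts and 30.1% of the heavy polysome counts at 0 h, and the 558 held 0.724% and 8.85%. Both sets were chosen from these same libraries, so the direction of these shares follows from the choice. Feature c1083535_g6 was among the most abundant, with 2859744 counts in free/RNP and 202736 in heavy polysomes over both replicates, a log2 fold change of −4.06 (SE 0.50). Feature c1092509_g3 had a log2 fold change of −4.31 (SE 0.62). In the other direction, c1086461_g2 had a log2 fold change of 4.16 (SE 0.61), from 116 and 23.2 CPM in heavy polysomes and 4.3 and 3.51 CPM in free/RNP (replicates 1 and 2), and c1035589_g1 of 4.39 (SE 0.84), from 106 counts in heavy polysomes and 6 in free/RNP. The 4 adjusted p-values were between 6.47e-08 and 0.000268 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With a replicate block 1391 features were higher and 1876 lower in heavy polysomes, and with TMM factors set on the filtered-table features 1031 and 923, which turns the balance and loses c1086461_g2. The count on the same features was 361 (171 higher, 190 lower) without the heavy polysome library of replicate 1, where c1035589_g1 was lost. Without the free/RNP library of replicate 1 or 2 it was 2235 (477 higher, 1758 lower) and 558 (240 higher, 318 lower), and c1086461_g2 was lost. With the filter rerun the balance turned without the heavy polysome library of replicate 1 (226 higher, 172 lower) and without the free/RNP library of replicate 2 (305 higher, 239 lower). With ERCC totals as library sizes and a replicate block 74 features were higher and 2141 lower, c1035589_g1 was lost, and the median over all tested features moved from 0.33 to −0.36. Without a filter on low counts 27 features were higher and 21 lower, and c1035589_g1 and c1092509_g3 were lost. Using only the libraries compared gave 84 higher and 175 lower. Over all edgeR and DESeq2 alternatives with calls, 3.34 to 56.8% of them were higher in heavy polysomes. On these features and without the heavy polysome library of replicate 1 or 2, the log2 fold change of c1086461_g2 was 2.54 and 5.06 and that of c1035589_g1 was 3.12 and 5.30. That of c1083535_g6 was −4.75 without the library of replicate 1, and that of c1092509_g3 was −4.91 without that of replicate 2.

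Gene counts per ERCC spike-in count gave the amount of RNA relative to the spike-in. In heavy polysomes the ratio of 24 h to 0 h was 1.47 (95% interval 1.44 to 1.5) in replicate 1 and 1.52 (1.23 to 1.88) in replicate 2. In light polysomes it was 1.01 (0.996 to 1.03) and 0.909 (0.74 to 1.12), and in free/RNP 0.96 (0.925 to 0.996) and 1.38 (0.979 to 1.96). The input ratio was 1.5 (1.47 to 1.53) in replicate 1 and 0.511 (0.346 to 0.743) in replicate 2, opposite directions. Without the most abundant feature the free/RNP ratio of replicate 1 turned to 1.08 and that of replicate 2 was 1.01, and by the median over ERCC rows the input ratio of replicate 2 was 0.808. Replicate 1 held 5258 to 70675 ERCC counts per library and replicate 2 held 43 to 212, so replicate 2 is far less precise, and the intervals leave out errors in adding the spike-in. With ERCC totals as library sizes and a replicate block, edgeR called 1956 features higher and 61 lower in heavy polysomes. Without the block it called none in any of the 7 comparisons, with 0 to 45 features at an unadjusted p under 0.05, since gene counts per ERCC count differed between the replicates from 462 to 198130 in input at 0 h.

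**Figure D5:**
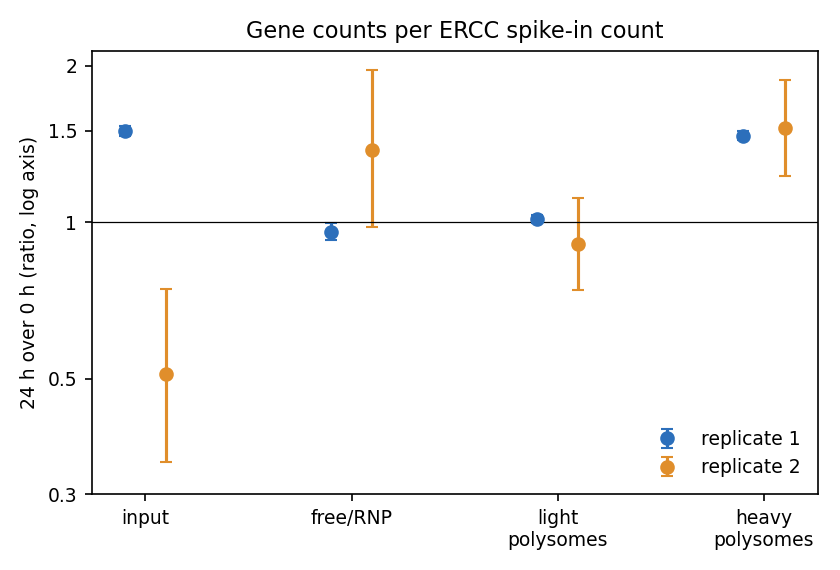
Ratio of gene counts per ERCC count at 24 h over 0 h (vertical axis, log scale) for each kind of sample (horizontal axis). Points are replicates 1 (blue) and 2 (orange) and bars are exact 95% intervals for counting error. Heavy polysomes lay above 1 in both replicates, at 1.47 and 1.52, while input lay at 1.5 and 0.511.

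In the authors' deposited normalized values, the share of a feature's signal found in each pool could be followed over the 8136 features of the filtered table. The median heavy polysome share rose from 17.9 to 21.5% in replicate 1 and from 24.6 to 29.8% in replicate 2. The median light polysome share fell from 27.3 to 22.3% and from 37.8 to 29.4%. The median free/RNP share was 53.4 and 54.9% in replicate 1 and 35.7 and 39.4% in replicate 2. The heavy polysome share was higher at 24 h in both replicates for 4290 features (52.7%) and lower in both for 1472 (18.1%), where independent signs at the rates of each replicate would put 45.3% and 10.6%. These are values of single libraries with no test, and all features of a replicate share its spike-in scaling. Without the subtracted offsets of the deposited values, the median free/RNP share of replicate 1 went from 56.7 to 49% instead, and the heavy polysome share was higher in both replicates for 5250 features.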

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

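The use of gene counts per ERCC count to weigh the excess in heavy polysomes was chosen after the result was seen, as were the tests with ERCC totals and a replicate block, with TMM factors set on the filtered-table features, on the calls kept by the deposited filter and without 1 library on the features of the main fit. The change from 0 h to 24 h differed between heavy polysomes and input for 1 feature (c1061563_g2, log2 difference 3.16), by the interaction contrast. It differed between heavy polysomes and free/RNP for 174 features, among them c1055716_g1 with a log2 difference of 4.73, c1068963_g2 with 4.54 and c1056993_g1 with −2.66. In simulated data with no feature changed beyond 200 at 2-fold, the heavy-to-input contrast made 24 false calls in a fit without a block. The data gave 1 call in such a fit. The simulated libraries lacked the shared lysates and days of the data, so this cannot decide whether that call is false. With a replicate block that contrast called 139 features, among them c1061563_g2 (adjusted p = 7.69e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

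In heavy polysomes 92.1% of the called features were higher at 24 h. The shallow 0 h library of replicate 1 was not the whole cause, since without it 80.4% were higher with the filter rerun and 88.2% on the features of the main fit. Whether the centring of the normalization caused the excess was not decided, since the share was 51.3% when only the features of the deposited filtered table were tested and 47.2% when these features set the TMM factors for all, but TMM centres the features it is set on. The filter left out 512 of the 2181 raised features and 118 of the 186 lowered ones, a larger part of the lowered. Of those left out, 244 raised and 2 lowered features had a count of 0 in a heavy polysome library at 0 h. With the reported scaling 1669 of the called features it kept rose and 68 fell. Gene counts per ERCC count rose to 1.47-fold and 1.52-fold in replicates 1 and 2, but this could not decide on a general increase of RNA as the cause. TMM scaling takes out an even rise of all features of a library, so such a rise cannot explain an excess seen after that scaling. With ERCC totals and a replicate block 97.0% of the called features were higher, but the same ERCC totals enter the ratios, so this is no separate evidence. Opposite input ratios also left the spike-in scale uncertain.

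The difference between the changes in heavy polysomes and free/RNP grew with the mean level of a feature. Pulling of low counts toward 0 by the prior count was argued against by counts summed within level classes, where the difference of features above 5 was still larger than that of features under 3 by at least 0.47 on the log2 scale in both replicates. Whether material found mainly in input and present in heavy polysomes at 0 h was a cause was not decided. Features whose input level was over 4 times the mean of free/RNP and light polysomes were left out. The gap was then still at least 0.37, but it had shrunk, from 0.47 to 0.37 in replicate 2 and from 0.62 to 0.42 in replicate 1. Such material may also add reads to features below that cutoff, which this test could not remove. In replicate 2 the summed difference was larger for features between 3 and 5 (0.74) than above 5 (0.53), so the trend of plain sums was not steady. Medians over blocks of 50 features did rise from class to class. For features under 3, between 3 and 5 and above 5 they were −0.08, 0.52 and 0.71 in replicate 1. In replicate 2 they were 0.04, 0.74 and 1.19. No biological explanation was tested.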

How the results depend on the processing

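Settings that combine a scaling or row choice with the replicate block, TMM factors set on the filtered-table features, leaving out a library on the features of the main fit, and gene counts per ERCC count without the most abundant feature or on the filtered-table features were chosen after seeing the data. Counts below are features past the threshold, in the order input, free/RNP, light polysomes, heavy polysomes, heavy relative to input, heavy relative to free/RNP, and heavy against free/RNP at 0 h, where the reported counts were 1187, 943, 1881, 2367, 1, 174 and 1366. Unless a cause is given, the cause of a change was not tested. A replicate block gave 2379, 2208, 3716, 4639, 139, 1372 and 3267, and included every feature called without it. A block per lysate gave 322, 1775 and 3735 for the last 3. ERCC totals as library sizes gave 0 in all 7, from the spread of spike-in yield between replicates, and with a replicate block 713, 898, 827, 2017, 5, 68 and 2215. Without a filter the counts were 310, 183, 406, 419, 1, 0 and 48, with 468765 features in the adjustment. A filter of 50 counts in 2 libraries gave 1534 in free/RNP, and 0, 49 and 2473 for the last 3. On the filtered-table features the last 3 were 0, 52 and 2242, and with a replicate block input, free/RNP and the last 2 were 1957, 1960, 447 and 2992. With TMM factors set on these features the count for heavy relative to free/RNP was 70. Using only the libraries compared, with the filter rerun (15042 to 40226 features), gave 2024 in input, 0 for heavy relative to free/RNP (1697 at an unadjusted p under 0.05) and 259 for heavy against free/RNP at 0 h. DESeq2 gave 1737 in free/RNP and 46, 476 and 2720 for the last 3. Limma on the deposited normalized values gave 0, 1, 0, 0, 0, 0 and 0, with 0 to 99 features at an unadjusted p under 0.05, and with a replicate block 11, 46, 21, 45, 0, 0 and 1. Where edgeR or limma gave 0 for the heavy relative to input contrast, 652 features had an unadjusted p under 0.05 with the stricter filter, 490 on the filtered-table features and 0 and 2 with limma without and with the block. RLE size factors kept all 7 counts within 1.5 times.

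Leaving out 1 library reran the filter, which then passed 56943 to 64927 features, so that library and filter changed together. It gave 346 to 657 features in input, 544 to 1004 in free/RNP, 724 to 1671 in light polysomes, 730 to 2258 in heavy polysomes, 0 to 6 for heavy relative to input (928 to 3329 at an unadjusted p under 0.05 where the count was 0), 12 to 1121 for heavy relative to free/RNP and 398 to 1777 for heavy against free/RNP at 0 h. On the 43215 features of the main fit the ranges were 486 to 718, 542 to 1055, 666 to 1071, 987 to 1656, 0 to 1 (930 to 2617 at an unadjusted p under 0.05 where the count was 0), 3 to 1084 and 361 to 2235. The lone library of a group was then assumed to vary like the other groups. No named feature changed direction in any setting. Of the 24 named results, 24 passed the threshold with a replicate block, 22 with RLE size factors, 22 by DESeq2, 21 with only the libraries compared, 20 with the stricter filter, 20 with TMM factors set on the filtered-table features, 18 without a filter and 0 with ERCC totals (20 with a replicate block added). Of those in the filtered table, 3 of 4 passed on its features alone (4 with the block) and 0 of 4 by limma (1 with the block), and a block per lysate kept 8 of 8. Leaving out 1 library kept 84 of 112 such calls with the filter rerun and 80 of 112 on the features of the main fit. For gene counts per ERCC count, the ratio in free/RNP replicate 1 turned from 0.96 to 1.08 without the most abundant feature. In input replicate 1 it was 1.57 as a median over the 3 ERCC rows with 10 counts in every library, 1.67 without the most abundant feature and 1.43 on the filtered-table features, and in input replicate 2 the first of these was 0.808. In light polysomes replicate 1 the same 3 values were 1.04, 1.09 and 0.992, and heavy polysomes replicate 1 gave 1.74 without the most abundant feature. Gene list tests and sums over shared symbols were not run, since no symbols were given. Depth was lowest in replicate 1 for both polysome pools at 0 h, which limits calls on features of few counts there.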

Other observations

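The test of 0 h ratios across replicate numbers was chosen after the relation was seen. A class of 14863 features was found mainly in input, with an input level over 4 times the mean of free/RNP and light polysomes. It held 5.53 to 7.02% of the input counts, 0.247 to 0.478% of the free/RNP counts and 0.482 to 0.677% of the light polysome counts. In heavy polysomes it held 2.96% and 2.2% of the counts at 0 h (replicates 1 and 2) and 1.46% and 0.977% at 24 h, lower at 24 h in both replicates. Most of the class (14669 features) had an average log2 CPM under 3. The class was defined from these libraries after they were seen, and no test was run on its share.

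The difference between the features that rose and those that fell in input was not tested. Those that rose in input had a median log2 difference of 0.63 between heavy polysomes and free/RNP, against 0.58 (95% range 0.51 to 0.64) in 10000 random lists matched on mean level. Those that fell in input had a median of 0.30 against 0.52 (0.32 to 0.71), at the 1.79 percentile of matched lists. These ranges describe these libraries and do not test the conditions.

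Features with the lowest log2 ratio of heavy polysomes to free/RNP at 0 h seemed to have the largest differences between the changes in heavy polysomes and free/RNP. With this 0 h ratio and the difference taken from the same replicate number, Spearman's rho across the 8136 features of the filtered table was −0.38 and −0.458. With the 0 h ratio from one replicate number and the difference from the other, rho was 0.0131 and −0.0956. The relation may therefore come from the same 0 h libraries entering both quantities. No biological explanation was tested.

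The deposited normalized values subtracted an offset after division by the spike-in slope. In heavy polysomes at 24 h, replicate 1, the offset was −16.5, so that features with counts under 63.5 fell below 0, and in light polysomes at 24 h, replicate 1, it was −15.3, with the limit at 75.9 counts. Of the gene rows, 15264 had a count in all 16 libraries, 8240 had a deposited value above 0 in all, and 8468 would have one with the intercept removed before division. The median heavy polysome change of replicate 1 over the filtered table was 0.87 on the log2 scale as deposited, 1.26 with the intercept removed first and 1.38 without the offset, while in replicate 2 it was 0.73 in each. The multipliers of the 24 h input libraries differed from their spike-in slopes by factors of 0.655 in replicate 1 and 1.18 in replicate 2, for which the values gave no source. All other multipliers equalled the slopes.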
